A study of Mus musculus with 22 samples.

How the data were processed

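Gene expression was measured in 22 end-stage mammary tumours of mice, each on its own array with 2 channels. Per the labels, total RNA of the tumour was labelled with Cy5 and total RNA of whole mouse, the common reference, with Cy3, in the same dye orientation on every array. Every ratio is therefore tumour over reference. The reference cancels when tumours are compared only where its channel is alike on the arrays, which did not hold for 3 arrays of the WAP_T121 tumours. A dye effect specific to a probe also does not cancel within a single tumour's ratio. Groups were read from the titles and fall into 9 genotypes. T121 is a fragment of the SV40 large T antigen that inactivates the Rb family of proteins. MMTV and WAP are promoters active in mammary epithelium, and coco and cohet mark conditional alleles that Cre recombinase removes from both copies or from 1 copy. A title with p53cococ was read as p53coco, and a title with TgMFT21 as TgMFT121. The titles carry no replicate numbers, so tumours were numbered in the order of their records and the numbers pair nothing. Strain names also differ: the tumour with WAP_T121 alone is labelled BALBc, the WAP_T121 tumours with a p53 genotype B6D2F1, and all others mixed. The titles of the TgMFT121 tumours end in the name Malini and all others in SIMIN. Wherever TgMFT121 tumours are used, this difference cannot be told apart from their line. Each title holds a number or code of its own, but the labels do not say whether tumours of a group came from separate animals. The p-values therefore measure the spread between these samples.

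The deposited scanner tables hold spot and local background intensity of both channels on a linear scale, per the file headers, with 22575 spots per array. They also hold intensities that the authors had normalized by lowess within each array. The deposited matrix holds, per the file headers, the log2 ratio of the lowess-normalized tumour channel over the reference channel, with spots the authors had flagged left empty. The lowess software, the scanner and its settings are not given in the sources used here. Each column of that matrix was set against the scanner values of the same array. It matched in direction and scale and showed no centring across arrays, with column medians from -0.03 to 0.01. Its correlation with the renormalized log2 ratios ran from 0.860 to 0.997 across probes.

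From the raw intensities, background was corrected with normexp at an offset of 50, and each array was normalized by loess with control and flagged spots at weight 0, in limma 3.58.1 under R 4.3.3. No step between arrays was applied. Flagged spots, 2 to 240 per array, were set to missing, and 1910 control spots were left out, which left 20665 probes. Of these, 18055 had 1 gene symbol in the platform table, 16 had several and 2594 had none. Of 18218 named probes, controls included, 18175 were found by Entrez number in the gene table and 0 symbols needed updating. A probe counted as above background where its tumour signal exceeded the local background by over 2.6 background SDs. Probes that did so on at least 5 arrays were kept, 13502 in all. A gene was represented by its probe of highest mean intensity, which gave 11418 genes. Where a gene was not above background in any tumour of a group, its difference is given only as a lower bound of the fold. That bound is of the tumour channel alone, while the adjusted p beside it is that of the fit on the log2 ratios. The bound sets the bright group's mean tumour channel against the dim group's floor, the higher on each array of the lowest signal above background and the probe's own signal. It leaves out the reference channel, so it can exceed the fold of the log2 ratios, and it is open to dye bias. No fold is given where both groups were below background or the bound was under 1.

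Each comparison was tested with lmFit and eBayes of limma on the log2 ratios, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The Brca1 comparison used only its 13 tumours. The others used all 22 arrays with a mean per group, because several groups hold 1 tumour, which is then assumed to vary like the other groups. Fold changes are differences of mean log2 ratios given with their standard error (SE). The 23 gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and adjusted over the lists. For the Brca1 comparison each list was also scored per tumour as the mean log2 ratio of its measured members. These scores were compared by a two-sided exact permutation test over all 1287 splits, whose smallest possible p is 0.000777. The lists covered S-phase and E2F targets, mitotic genes, p53 targets, homologous recombination, luminal, basal and squamous markers, epithelial junctions, mesenchymal transition, milk genes, T cells, B cells, macrophages, interferon response, fibroblasts and matrix, adipocytes, endothelium, skeletal muscle, hypoxia and glycolysis, neuroendocrine markers, the Notch pathway, haemoglobins, and oncogenes of mammary amplicons. 2 older symbols that could mean several genes were left out of the lists.

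Named genes follow a rule fixed, with the groups, tests, lists and other settings to try, before the data were examined. Brca1, Rb1, Rbl1 and Rbl2 are given in every comparison, and the gene that encodes p53 was not analysed here. In the Brca1 comparison the rule takes the 10 largest changes in each direction past the threshold, filled up by smallest unadjusted p where fewer passed, and up to 4 members of each list by smallest p. In the other comparisons it takes the 5 largest in each direction past the threshold and the 3 members with smallest p of each list that passed camera. Names that are not gene symbols were skipped.

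Arrays with adjacent array numbers were treated as 1 run, giving 9 runs, and run was tested as a batch. Runs 1 to 4 hold the WAP_T121 and TgMFT121 tumours and run 5 both cohet tumours and p53coco tumour 1. Run 6 holds p53coco tumour 2, runs 7 and 8 Brca1coco tumours, with the tumour lacking T121 in run 8. Run 9 holds Brca1coco tumours 7 and 8 and p53coco tumours 3, 4 and 5, and is the only run with both groups of the Brca1 comparison. The other settings fixed at that point were no background subtraction, median centring in place of loess, Aquantile, no filter on dim probes, the mean of a gene's probes, the authors' matrix, array weights, run as a fixed or random block, the values within a run, other sets of arrays, an estimated correlation in camera, and leaving out each tumour in turn. Added after seeing the data were quantile normalization over all channels, the TgMFT121 tumours in place of the p53coco tumours, and leaving out the 3 arrays of run 1. The lists that passed camera outside the Brca1 comparison were also put through each setting only after the data were seen, and run as a block was then combined with an estimated correlation.

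The procedure was tested on simulated data with 200 changed genes among 11418 in 10 sets. In the Brca1 design it recovered 14.8% of genes changed 1.5-fold, 52.8% at 2-fold, 82.2% at 3-fold and 91.2% at 4-fold, with 5.79% of calls false. At 4-fold it recovered 51.2% in the T121 design, 42.6% for p53 dose in MMTV_T121 tumours, 69.4% for WAP_T121 against MMTV_T121, 64.8% for TgMFT121 and 34.4% for p53 dose in WAP_T121 tumours. Independent simulated genes shifted by 1 log2 unit gave a list call in 10 of 10 sets, in which 5 calls of other lists, left unshifted, were made as well. Real list members are correlated, which the preset correlation understates. Tables were read with jsonlite 2.0.0, and figures drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15.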

Results

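Tumour RNA of 22 mouse mammary tumours was hybridized against a common reference to compare tumours in which the Rb family pathway, p53 and Brca1 had been perturbed in different combinations. The main groups were 8 tumours of MMTV_T121_WAPCre_p53coco_Brca1coco mice (here Brca1coco) and 5 of MMTV_T121_WAPCre_p53coco mice (here p53coco). There were 2 TgMFT121_WAPCre_p53coco tumours and 2 WAP_T121_p53null tumours. WAP_T121, WAP_T121_p53het, MMTV_T121_MMTVCre_p53cohet, MMTV_T121_WAPCre_p53cohet and WAPCre_p53coco_Brca1coco were represented by 1 tumour each. The number of arrays and their brightness limited precision. The share of probes above background in the tumour channel ran from 15.7% to 83.1%, with 21.2% to 69.7% in the Brca1coco and 43.3% to 64.9% in the p53coco tumours. The reference channel should be alike on all arrays. Its rank correlation with the median of the other arrays was 0.932 to 0.984 on 19 arrays and 0.472 to 0.779 on the other 3, which carried WAP_T121 tumour 1, p53null tumour 1 and the p53het tumour. Log2 ratios correlated across genes at 0.651 to 0.934 between Brca1coco tumours and 0.417 to 0.855 between p53coco tumours.

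**Figure D1:**
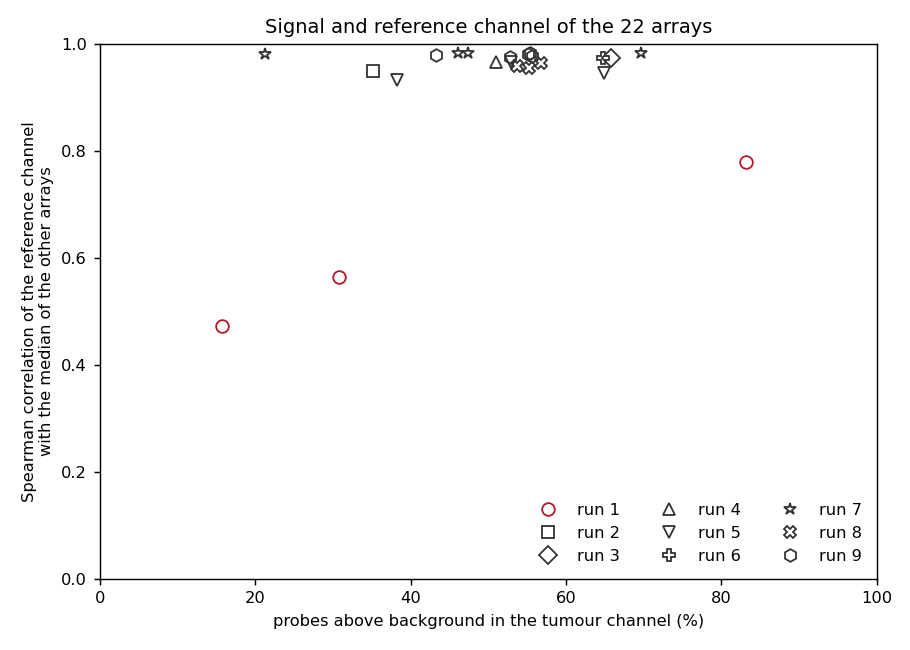
Percentage of probes above background in the tumour channel (x axis) against the Spearman correlation of the reference channel with the median of the other arrays (y axis), with 1 point per array and symbols for the array run. The 3 arrays of run 1 lie at 0.472 to 0.779 and the other 19 at 0.932 to 0.984.

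The first comparison asked what differs when Brca1 is deleted in addition to p53 in T121 tumours. The Brca1coco tumours had higher Mgst2, a microsomal glutathione transferase, and lower Xdh and Glo1. Xdh encodes xanthine dehydrogenase, which also coats milk fat globules, and Glo1 encodes the glyoxalase that detoxifies methylglyoxal. Mgst2 rose by 2.30 log2 units (SE 0.34, adjusted p = 0.0331), from -0.75 ± 0.53 (SD, n = 5) to 1.55 ± 0.71 (SD, n = 8). Xdh fell by 2.43 (SE 0.35, adjusted p = 0.0331), from 2.91 ± 0.73 to 0.49 ± 0.62, which is 5.37-fold. Glo1 fell by 1.38 (SE 0.20, adjusted p = 0.0331), from -0.35 ± 0.34 to -1.73 ± 0.36. Each of the 3 lay beyond the p53coco mean in 8 of 8 Brca1coco tumours.

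These were the 3 genes of 11418 that passed in limma, 1 higher and 2 lower, while 1306 had an unadjusted p below 0.05. Next by unadjusted p, none passing, the higher side held Tiam2, an exchange factor for Rac, at 1.39 (adjusted p = 0.0558) and Ecrg4 at 3.67 (adjusted p = 0.0567). The transcription factor Twist1 was at 1.63 (adjusted p = 0.0567), Eif1ad at 0.89, Fam204a at 0.88, Lgals7, a galectin of stratified epithelia, at 2.65, Wdr70 at 1.08, Tm4sf1 at 1.64 and Afap1l2 at 1.20. The lower side held Apol9b at -1.17, Rab7b at -1.26, the adaptor subunit Ap3d1 at -0.89, the disulfide isomerase Pdia6 at -0.98, Gpnmb at -1.24 and Rapgef5 at -0.82. Stat5a, a transcription factor of the prolactin response, was at -1.65 (adjusted p = 0.0579). Tln2 was at -1.16, but its other probe was at -0.02. The Brca1 probe read 0.95 ± 0.47 in Brca1coco and 0.94 ± 0.67 in p53coco tumours (difference 0.01, SE 0.29, adjusted p = 0.995). Where that probe lies relative to the deleted part is not known here, so it does not check the genotype. Rb1 was at -0.71 (SE 0.25, adjusted p = 0.306), Rbl1 at -0.55 (adjusted p = 0.574) and Rbl2 at -0.20 (adjusted p = 0.736).

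The call of these genes was fragile. With array run as a block limma called 0 genes (923 unadjusted), although Mgst2 differed by 2.49 (SE 0.57), Xdh by -2.31 (SE 0.58) and Glo1 by -1.37 (SE 0.34), values that rest on the 2 Brca1coco and 3 p53coco tumours of run 9. Within that run alone 24 genes passed. Against the TgMFT121 tumours in place of the p53coco tumours Mgst2 was at 0.21, Xdh at -0.58 and Glo1 at -0.20, and 0 genes passed (1078 unadjusted). With run as a block Lgals7 was at 0.87, Wdr70 at 0.21 and Rbl1 at 0.18. Median centring gave 0 (913 unadjusted) and array weights 414. Leaving out Brca1coco tumour 4, 5, 6, 7 or 8 gave 0 (1001 to 1340 unadjusted). It was 10 without p53coco tumour 2, 7 without Brca1coco tumour 1, 5 without Brca1coco tumour 2 and 1 without p53coco tumour 4. None of Mgst2, Xdh and Glo1 passed without p53coco tumour 1 or 4, Mgst2 and Glo1 did not without p53coco tumour 3 or Brca1coco tumour 3, and Xdh and Glo1 did not without p53coco tumour 5.

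**Figure D2:**
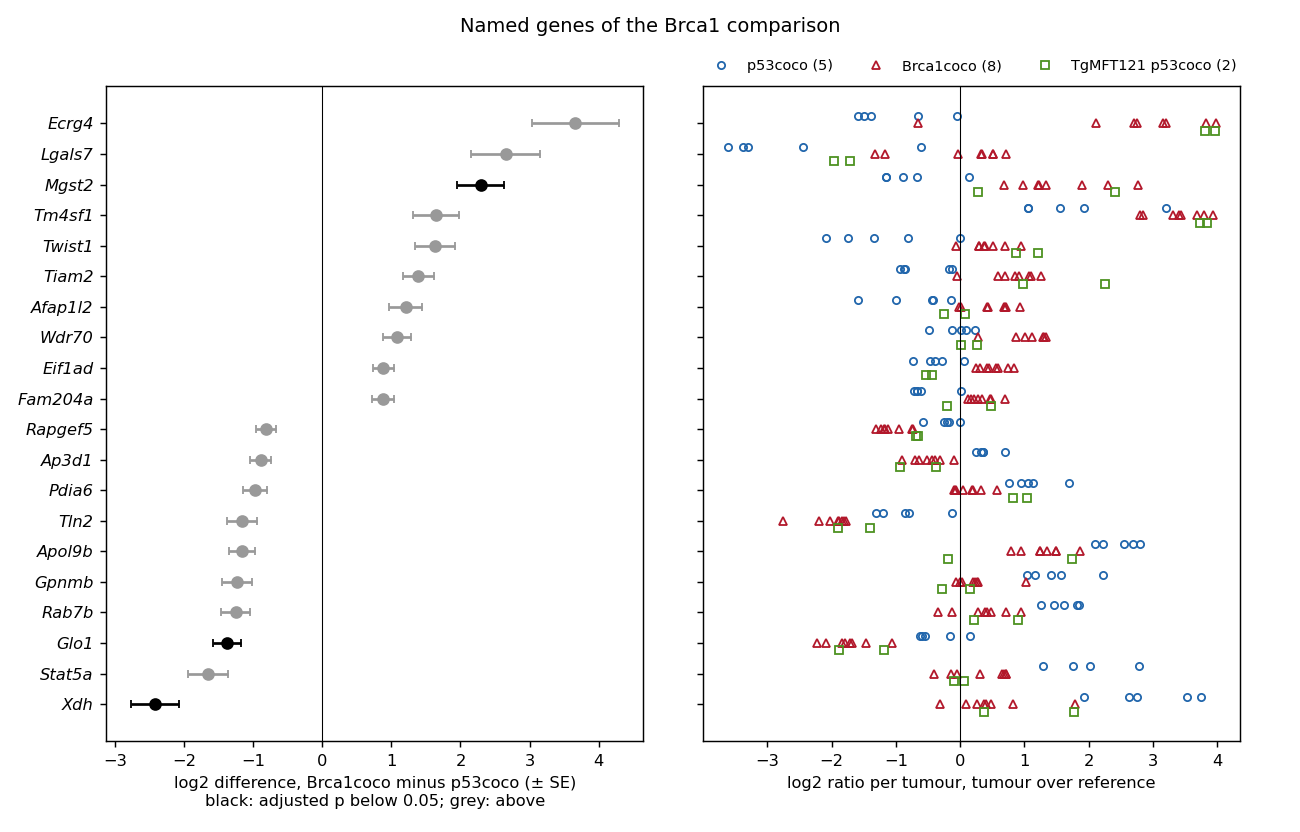
Left, log2 difference between Brca1coco (n = 8) and p53coco (n = 5) tumours with SE bars for the 20 genes of the rule, black where the adjusted p was below 0.05. Right, log2 ratio of tumour over reference for each tumour of both groups and of the 2 TgMFT121 p53coco tumours. Mgst2 (2.30), Glo1 (-1.38) and Xdh (-2.43) are black.

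Interferon response genes stood lower in Brca1coco tumours in all 20 members measured, by a mean of -1.03. The list passed camera (adjusted p = 1.02e-11; adjusted p = 0.477 with an estimated correlation), and 13 members fell when adjusted over the list alone, while none passed over all genes. Oas2, a sensor of double-stranded RNA, fell by 2.03 (SE 0.49, adjusted p = 0.0145, adjusted over the list alone), and Ifit3 by 1.60. Irf9 and Stat2, partners in the transcription factor of the type I interferon response, were at -0.88 and -1.19 and fell adjusted over the list alone (adjusted p = 0.0176). The score per tumour averaged 0.59 ± 0.48 (SD, n = 8) against 1.61 ± 0.78 (SD, n = 5), with an exact permutation p of 0.0155 and an adjusted p of 0.119. It lay below the p53coco mean in 8 of 8 Brca1coco tumours, but p53coco tumour 3 scored 0.56, below the Brca1coco mean. With run as a block, which equals the difference within run 9, the score differed by -1.27 (95% interval -2.45 to -0.09). Only the difference rests on run 9 alone, as the interval also takes its spread from the Brca1coco tumours of runs 7 and 8. Against the TgMFT121 tumours in place of the p53coco tumours the list passed in the opposite direction, at 0.55 (camera adjusted p = 0.000614), and with them added to the p53coco tumours it was at -0.58.

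Milk genes were lower in 15 of 16 members, by a mean of -1.58 (camera adjusted p = 2.56e-07; adjusted p = 0.477 with an estimated correlation). Adjusted over the list alone, 2 members fell: Xdh and Btn1a1, the butyrophilin of milk fat membranes. Btn1a1 was at least 1.80-fold lower, being above background in 0 of 8 Brca1coco tumours. The caseins Csn2 and Csn1s2a were at -3.34 (SE 1.21) and -3.33 (SE 1.30) and did not pass. The score averaged 1.11 ± 1.12 against 2.68 ± 1.26, below the p53coco mean in 7 of 8 Brca1coco tumours (exact permutation p = 0.042, adjusted p = 0.193). With run as a block the score differed by -1.40 (95% interval -4.29 to 1.49), and the list was at 0.17 against the TgMFT121 tumours.

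Adipocyte markers were lower in 10 of 10 members, by a mean of -1.22 (camera adjusted p = 3.69e-06; adjusted p = 0.477 with an estimated correlation). Adjusted over the list alone, 6 fell, among them the lipid droplet gene Cidec by 2.12, the lipoprotein lipase gene Lpl by 1.65, the adiponectin gene Adipoq by 1.57 and Cd36 by 1.71 (-2.82 with run as a block). With run as a block the score differed by -1.64 (95% interval -3.21 to -0.08, its spread again taken in part from other runs than run 9). Over all 13 tumours the exact permutation adjusted p was 0.119, and 7 of 8 Brca1coco tumours lay below the p53coco mean. T cell markers were lower in 10 of 11 members, by a mean of -0.41 (camera adjusted p = 0.00346; adjusted p = 0.482 with an estimated correlation). None passed over the list alone, where Gzmb was at -0.74 and Cd6 at -0.62. Their score gave the smallest exact permutation p of the 23 lists, 0.00311 (adjusted p = 0.0715). It averaged -0.06 ± 0.11 (SD, n = 8) in Brca1coco tumours, of which 8 of 8 lay below the p53coco mean. The T cell list no longer passed camera within run 9 (-0.15, adjusted p = 0.229), with run as a block (adjusted p = 0.287) or without p53coco tumour 2 (-0.21, adjusted p = 0.0769), whose T cell score was 1.16 against 0.02 to 0.29 in the other 4. Against the TgMFT121 tumours the adipocyte list was at 0.36 (-0.77 with them added to the p53coco tumours) and the T cell list at 0.044.

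Skeletal muscle genes were lower in 15 of 15 members (mean -0.94, camera adjusted p = 0.0112; adjusted p = 0.884 with an estimated correlation), with Myoz1 at -1.06 and Myh2 at -1.90, neither passing. Endothelial markers were lower in 12 of 13 (mean -0.37, camera adjusted p = 0.0451; adjusted p = 0.884 with an estimated correlation), with Ramp2 at -0.76 and Vwf at -0.68. Both calls were lost without p53coco tumour 3, whose muscle score was 1.46 against -3.22 ± 0.96 in the other 4. Without it the muscle list was at -0.0080 and the endothelial list at 0.038 (adjusted p = 0.785 for both). The endothelial call was also lost without p53coco tumour 4 or Brca1coco tumour 2, 3, 6, 7 or 8, and the list was at -0.67 without p53coco tumour 1. Mesenchymal transition genes were higher in 15 of 18 (mean 0.38, camera adjusted p = 0.0195; adjusted p = 0.884 with an estimated correlation). Twist1, and Foxc2 at 1.55, rose when adjusted over the list alone (adjusted p = 0.00124 and 0.0359), and Foxc2 was at 2.65 with run as a block. The list no longer passed without p53coco tumour 1 (0.17), 2 (0.31) or 5 (0.26) or Brca1coco tumour 1 (0.27), and was at 0.69 without p53coco tumour 3. Array weights ended the muscle (-0.16) and mesenchymal (0.18) calls, and TgMFT121 tumours added to the p53coco tumours ended these (-0.44 and 0.23) and the endothelial call (-0.28). With run as a block the mesenchymal list was at -0.017, muscle at -1.82 and endothelium at -0.97. Against the TgMFT121 tumours mesenchymal genes were at -0.14 and endothelial markers at -0.043, and muscle genes passed in the opposite direction, at 0.82 (camera adjusted p = 0.000801).

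The other 16 lists did not pass camera. B cell markers were at a mean of -0.54 (adjusted p = 0.051), where Cd79b (-1.23) and Jchain (-1.63) fell adjusted over the list alone (adjusted p = 0.0199 and 0.0468). The list was at -0.25 without p53coco tumour 2 and at -0.15 with run as a block, where Cd79b was at -0.83 and Jchain at -0.63. Macrophage markers were at -0.30 (adjusted p = 0.0672), with 13 of 15 lower and the complement gene C1qb at -0.56, and at -0.087 without p53coco tumour 3. Mitotic genes were at 0.14 (adjusted p = 0.114), with Mad2l1 at 0.98 and Mki67 at -0.79, and S-phase and E2F targets at 0.06 (adjusted p = 0.610), with Rfc4 at 0.66 and Tyms at -0.36. With run as a block the mitotic list was at 0.31 (camera adjusted p = 0.00219), S-phase at 0.24 (0.0258), macrophages at -0.68 (0.0032) and fibroblast genes at -0.94 (0.0032). With an estimated correlation none of these 4 passed in that fit (adjusted p = 0.759 for S-phase and adjusted p = 0.586 for the others). The 95% intervals of their scores in it held 0, at -0.42 to 1.03 for mitotic, -0.61 to 1.08 for S-phase, -1.94 to 0.58 for macrophage and -2.76 to 0.93 for fibroblast genes. Squamous genes were at 0.33 (adjusted p = 0.244), with Krt1 at 0.72, but at -0.36 within run 9. Neuroendocrine markers were at 0.21 (adjusted p = 0.361), fibroblast and matrix genes at -0.25 (adjusted p = 0.610), with Mmp2 at 1.39 and the proteoglycan gene Dcn at -1.62. Luminal markers were at -0.16 (adjusted p = 0.610), with Xbp1 at -0.57, and Notch pathway genes at 0.13 (adjusted p = 0.610). p53 targets were at -0.02 (adjusted p = 0.638), with Btg2 at -0.70 and Plk2 at 0.78. Homologous recombination genes were at -0.02 with Atm at 0.61, basal markers at 0.11 with Cnn1 at -0.95, junction genes at -0.05 with Pkp1 at 1.69, and haemoglobins at -0.17, each with an adjusted p of 0.670. Hypoxia and glycolysis genes were at -0.05 with Ldha at -0.71, and amplicon oncogenes at 0.00 with a median of -0.09, both with an adjusted p of 0.768. Several of these lists passed camera at the preset correlation when 1 tumour was left out, where no estimated correlation was tested. B cell markers did so without p53coco tumour 3 (-0.68), 4 or 5 or Brca1coco tumour 3, 4 or 5, and macrophage markers without p53coco tumour 1 or 5 (-0.51) or Brca1coco tumour 1, 3 or 4. Mitotic genes did so without p53coco tumour 1 (0.25) or 5 or Brca1coco tumour 1, and S-phase genes without p53coco tumour 1 (0.23) or 5. Luminal markers (-0.61) and junction genes (-0.55) did so without p53coco tumour 3, and squamous genes without p53coco tumour 5 (0.50). Fibroblast genes did so without p53coco tumour 1 (-0.55) and, in the opposite direction, without p53coco tumour 3 (0.23). In the tests of list scores 0 of 23 passed the exact permutation test after adjustment, and 7 passed without p53coco tumour 3 and 3 without Brca1coco tumour 3.

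**Figure D3:**
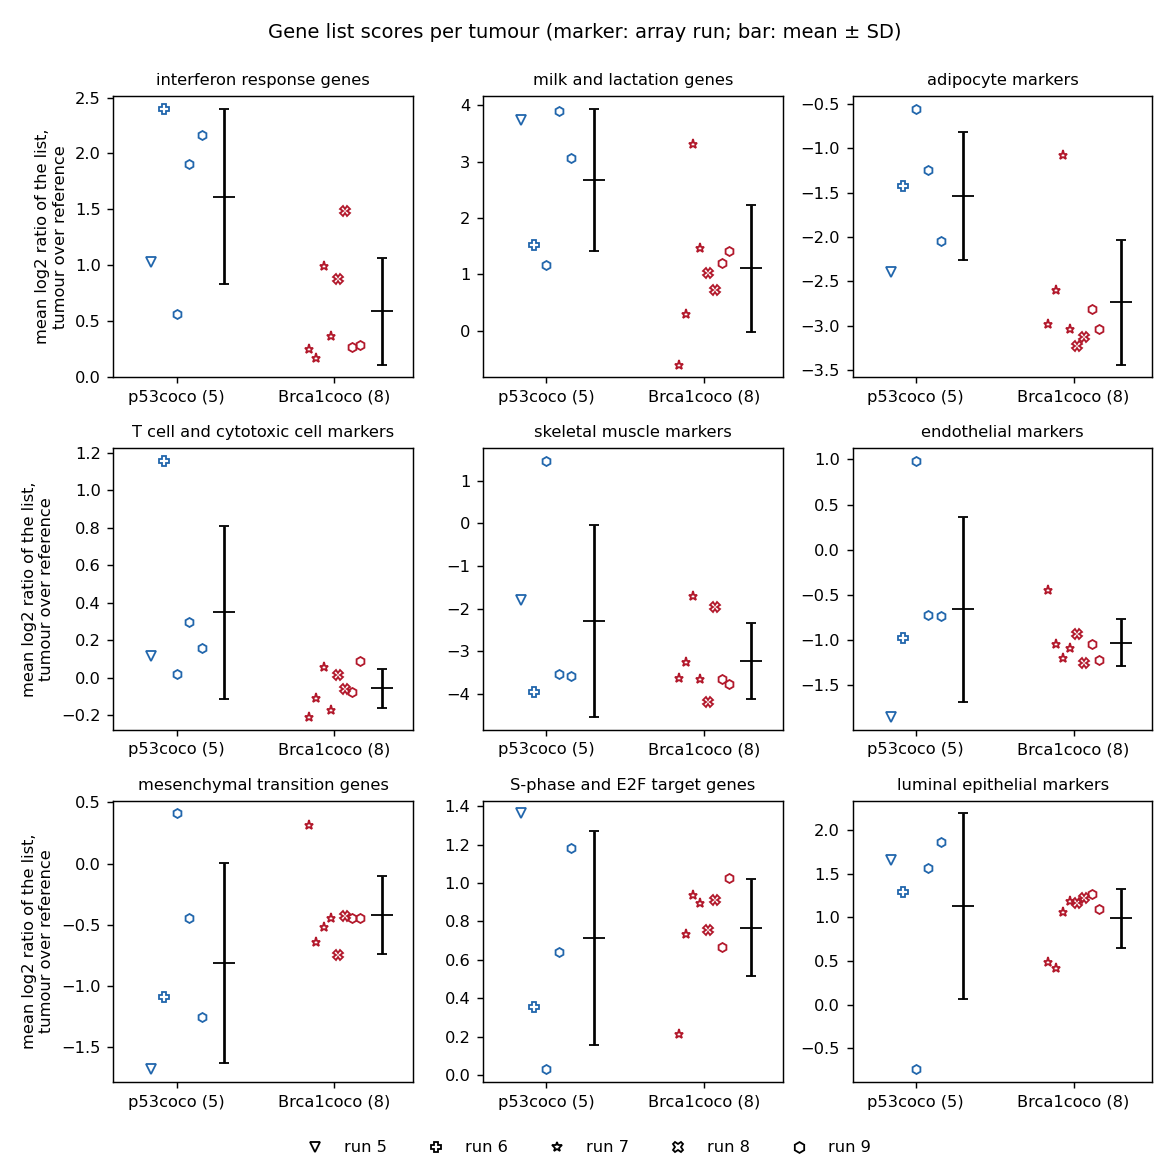
Mean log2 ratio of 9 gene lists (y axis) in each p53coco (n = 5) and Brca1coco (n = 8) tumour, with symbols for the array run and bars for mean ± SD. All 8 Brca1coco tumours lie below the p53coco mean for interferon response genes (1.61) and T cell markers.

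The role of T121 was asked by setting the 8 Brca1coco tumours against the single WAPCre_p53coco_Brca1coco tumour, which lacks it. Pnmt, the enzyme that makes adrenaline, was at least 1.03-fold higher (adjusted p = 0.00409), and the odorant receptor gene Olfr566 at least 1.16-fold (adjusted p = 0.0356). Both lay near background: Pnmt was above it in 1 of 8 tumours and 0 of 1, and Olfr566 in 3 of 8 and 0 of 1. The log2 signal of the tumour channel alone averaged 6.50 against 6.46 for Pnmt and 6.95 against 6.73 for Olfr566. Rb1 was at 0.53, Rbl1 at -0.45 and Brca1 at -0.10, and Rbl2, above background in 0 of 1 tumour without T121, was at least 1.11-fold higher, each with an adjusted p of 0.999. None of the 23 lists passed camera, and the smallest adjusted p was 0.105, for mitotic genes. Of 11386 genes 2 passed in limma, both higher, and 368 had an unadjusted p below 0.05. Within run 8 (2 tumours against 1) the ratios of both genes were higher too. Olfr566 did not pass with run as a block or without any 1 of Brca1coco tumours 2 to 8. The count was 0 with the authors' values (263 unadjusted), median centring (300) or quantile normalization (244), 1 with run as a block or without Brca1coco tumour 2, 3, 4, 6, 7 or 8, and 28 without the filter.

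p53 dose by genotype in MMTV_T121 tumours was addressed by 5 p53coco tumours against the single WAPCre_p53cohet tumour. Whether that tumour kept its other p53 copy was not measured. Milk genes stood lower in the p53coco tumours in all 16 members measured, by a mean of -2.36 (camera adjusted p = 8.57e-09; adjusted p = 0.824 with an estimated correlation). Btn1a1 fell by 4.01 (SE 0.59, adjusted p = 0.00737), which is 16.1-fold. Cel, a lipase also secreted into milk, fell by 2.76 (adjusted p = 0.0212), and the lactoperoxidase gene Lpo by 2.46 (adjusted p = 0.0496). These were the 3 members that passed over all genes, and 5 did adjusted over the list alone. The single heterozygous tumour had the highest milk score of all, 5.04, against 2.68 ± 1.26 (SD, n = 5).

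Outside that list the genes that fell included Sycn, a secretory granule gene, at -3.68, the growth factor binding protein gene Igfbp2 at -3.49 (adjusted p = 0.0116), the hair keratin gene Krt34 at -3.04 and Slc45a3 at -2.89. On the higher side were Smim3, at least 2.98-fold (adjusted p = 0.0363), and Ccdc71 at 1.46 (adjusted p = 0.00897). Rb1 was at -2.15 (SE 0.53, adjusted p = 0.0954), Brca1 at -1.41 (adjusted p = 0.429), Rbl2 at -0.63 and Rbl1 at 0.07. In limma 55 genes passed, 2 higher and 53 lower, and 966 had an unadjusted p below 0.05. Between the 2 tumours of run 5 Btn1a1 differed by -2.67, Sycn by -2.94, Igfbp2 by -3.72, Lpo by -1.40 and the milk list by -1.30. Adipocyte markers were at -0.98 (9 of 10 lower, camera adjusted p = 0.0983) and at -1.85 between those 2 tumours. With run as a block 8 genes passed, 5 higher and 3 lower, none of them among the genes named as higher or lower here. Lpo did not pass without p53coco tumour 3, 4 or 5 or without the 3 arrays of run 1, nor Smim3 without p53coco tumour 2, 3, 4 or 5. The count was 0 with the authors' values (780 unadjusted), 1 with median centring, which moved the median of all genes by 0.25, and 126 without the filter, and leaving out p53coco tumour 1, 3 or 5 gave 108, 36 and 35.

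The WAP_T121 and MMTV_T121 models were compared through 2 p53null and 5 p53coco tumours, which also differ in strain, p53 allele and array run. The p53null tumours had lower milk, S-phase and mitotic genes and higher squamous genes, and these 4 lists passed without any 1 of the tumours compared. The p53null arrays were dim, with 15.7% and 35.1% of probes above background in the tumour channel, against 43.3% to 64.9% for p53coco. Their S-phase score averaged -0.08 against 0.71, and their squamous score -0.40 against -1.83. Leaving out 1 tumour cannot test an effect of dim signal that both p53null arrays share. Milk genes were lower in 16 of 16 members (mean -2.68, camera adjusted p = 1.29e-06; adjusted p = 0.483 with an estimated correlation), and 7 fell adjusted over the list alone. Xdh fell by 2.94 (SE 0.52, adjusted p = 0.0199), Csn1s1 by 5.31 over the list alone, and Csn2 was at least 14.4-fold lower. S-phase genes were lower in 25 of 27 (mean -0.79, camera adjusted p = 1.29e-06; adjusted p = 0.483 with an estimated correlation), where the replication clamp gene Pcna fell by 1.91 (adjusted p = 0.021) and the thymidylate synthase gene Tyms by 1.22 (adjusted p = 0.0456), with 3 adjusted over the list alone. Mitotic genes were lower in 28 of 28 (mean -0.66, camera adjusted p = 5.3e-06; adjusted p = 0.483 with an estimated correlation), and 1, Aurka, fell adjusted over the list alone, by 0.99. Over all genes Xdh, Pcna and Tyms did not pass without p53null tumour 1, nor Tyms without p53null tumour 2 or p53coco tumour 1, 4 or 5.

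Squamous genes were higher in 12 of 12 members (mean 1.43) and neuroendocrine markers in 7 of 7 (mean 1.39), both with a camera adjusted p of 0.000118 (adjusted p = 0.483 with an estimated correlation) and 5 members past the threshold adjusted over the list alone. Among them Krtdap was at 2.99 and Krt10 at 2.62. The neuroendocrine members Scg3, Gap43 and Uchl1, 3 of the 5, were above background in 0 of 2 p53null tumours. Basal markers were higher in 13 of 17 (mean 0.94, camera adjusted p = 0.00201; adjusted p = 0.483 with an estimated correlation), with Krt17 at 2.96, Jag2 at 1.39 and Myh11 at 1.23 among 4 past the threshold adjusted over the list alone. Luminal markers were at -1.31 (camera adjusted p = 0.00615; adjusted p = 0.493 with an estimated correlation), where Xbp1 fell by 2.11 (adjusted p = 0.0274; adjusted p = 0.0769 without p53null tumour 2). Interferon genes were at -0.79 (0.00452), mesenchymal genes at 0.59 (0.0193), junction genes at -0.51 (0.0434), T cell markers at 0.39 (0.0434), muscle genes at -1.11 (0.0434), homologous recombination genes at -0.32 (0.0435) and macrophage markers at -0.66 (0.0441). Their adjusted p with an estimated correlation was 0.669 for mesenchymal and T cell genes, 0.729 for interferon and 0.730 for the other 4. Most of these calls depended on single tumours. Without p53null tumour 1 the neuroendocrine (0.60), interferon (0.0010), junction (-0.025) and macrophage (-0.28) lists no longer passed, while basal markers were at 1.92 and T cell markers at 0.90. Without p53null tumour 2 the same held for the basal (-0.038), T cell (-0.11), luminal (-1.10), homologous recombination (-0.28), mesenchymal (0.42) and muscle (-0.76) lists, while interferon genes were at -1.57, junction genes at -0.99, macrophage markers at -1.04 and neuroendocrine markers at 2.19. Muscle genes were at -0.17 without p53coco tumour 3 (adjusted p = 0.693), where junction genes were at -1.01 and mesenchymal genes at 0.90, and T cell markers were at 0.59 without p53coco tumour 2. Calls were also lost without p53coco tumour 1 (homologous recombination, junction, mesenchymal, T cell, muscle), 2 (junction, macrophage), 3 (T cell, macrophage), 4 (junction, T cell, macrophage) or 5 (homologous recombination, junction, mesenchymal, T cell). Quantile normalization ended the luminal (-1.11), interferon (-0.56), neuroendocrine (0.62), homologous recombination (-0.37), junction (-0.48), mesenchymal (0.16) and macrophage (-0.68) calls and put T cell markers at 0.74 and muscle genes at -1.75. Median centring ended the mesenchymal (0.24), junction (-0.74), macrophage (-0.82) and muscle (-1.05) calls and put homologous recombination genes at -0.58. The mesenchymal, junction, T cell, muscle, homologous recombination and macrophage calls were each lost under at least 1 further setting. Of these lists, Tnnc2 (-2.78), Mylpf (-2.65) and the macrophage receptor gene Cd14 (-2.89) fell adjusted over the list alone.

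Among single genes Igf1r, the receptor of insulin-like growth factor 1, was higher by 3.28 (SE 0.60, adjusted p = 0.0208), though its other probes gave 0.65 and 1.26. Cavin4 was higher by 3.15 and the cartilage gene Ucma by 3.04. Krt1 and Pzp also passed (adjusted p = 0.0393 and 0.0208), but neither was above background in the p53null tumours, and the other Krt1 probe was at -0.15. In the tumour channel Chil3, a chitinase-like protein of macrophages, was at least 15.1-fold lower, Amph, of synaptic vesicle endocytosis, at least 29.0-fold and Brinp1 at least 8.15-fold. Ppp1cb fell by 3.30. Myo1c was lower by a log2 ratio of -4.83, with a value in 1 of the 2 p53null tumours, while its log2 tumour channel was 8.54 against 7.14. Brca1, Rb1 and Rbl2 were above background in 0 of 2 p53null tumours. There Rb1 was at least 3.72-fold lower in the tumour channel, more than its log2 ratios differed, and did not pass on those ratios (adjusted p = 0.108). Brca1 was at least 1.17-fold lower and did not pass either (adjusted p = 0.179), and Rbl1 was at -0.82. In limma 139 genes passed, 53 higher and 86 lower (1889 unadjusted). Run and group cannot be told apart here, and the reference channel of p53null tumour 1 stood apart: without it 114 genes passed, 70 higher and 44 lower. Of the genes named here, Igf1r, Cavin4, Krt1, Pzp, Amph, Brinp1 and Ppp1cb (-2.19) did not pass without it, and Ucma (1.83), Chil3, Amph and Brinp1 did not without p53null tumour 2. Amph and Brinp1 did not without p53coco tumour 1, 2, 4 or 5, nor Krt1 without p53coco tumour 2. Leaving out p53null tumour 2 gave 709, and p53coco tumour 2, 3, 4 or 5 gave 81, 317, 75 and 91. Median centring gave 15 higher and 7 lower and moved the median of all genes by -0.17, and the count was 64 with run as a random block, 90 without background subtraction, 214 with the authors' values and 1277 with quantile normalization.

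A further T121 line was addressed by 2 TgMFT121 against 5 p53coco tumours, all with WAPCre and p53coco. Interferon response genes were lower in TgMFT121 tumours in 20 of 20 members, by a mean of -1.57 (camera adjusted p = 2.07e-14; adjusted p = 0.452 with an estimated correlation). Adjusted over the list alone 15 fell, among them Stat2 by 1.99, Oas2 by 2.55, and Irf7, the regulator of type I interferon genes, at least 2.63-fold lower. Adipocyte markers were lower in 9 of 10 (mean -1.57, camera adjusted p = 1.33e-05; adjusted p = 0.452 with an estimated correlation), with 6 past the threshold over the list alone, among them Fabp4, which fell by 2.91, and Lpl, by 2.39. Milk genes were lower in 14 of 16 (mean -1.75, camera adjusted p = 2.14e-06; adjusted p = 0.452 with an estimated correlation), where Xdh fell by 1.84 over the list alone.

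Muscle genes were lower in 15 of 15 members (mean -1.76, camera adjusted p = 3.91e-05; adjusted p = 0.605 with an estimated correlation), with Myh2 at -3.26, but the list was at -0.83 (adjusted p = 0.00868) without p53coco tumour 3. Hypoxia and glycolysis genes were lower in 15 of 17 (mean -0.65, camera adjusted p = 0.00192; adjusted p = 0.452 with an estimated correlation), with Ldha at -1.70 and Aldoa at -1.66. T cell markers were at -0.45 (0.00968; adjusted p = 0.553 with an estimated correlation), with Cd3e at -0.47, and haemoglobins at -0.87 (0.0479; adjusted p = 0.452 with an estimated correlation), where Hba-a1 fell by 1.69 over the list alone. Mesenchymal genes were higher in 14 of 18 (mean 0.52, camera adjusted p = 0.0212; adjusted p = 0.655 with an estimated correlation), where Twist1 rose by 2.24 at p = 0.00193 over the list alone. Calls of lists also depended on single tumours. T cell markers were at -0.25 without p53coco tumour 2 and -0.34 without TgMFT121 tumour 1, and hypoxia genes at -0.40 without TgMFT121 tumour 1, none passing. Mesenchymal genes did not pass without p53coco tumour 1 (0.31) or 2 (0.45) or TgMFT121 tumour 1 (0.37), and were at 0.84 without p53coco tumour 3. Haemoglobins no longer passed without p53coco tumour 2, 3 or 4 or either TgMFT121 tumour, with median centring, with the authors' values or with quantile normalization. Trabd, which fell by 1.53 (SE 0.18, adjusted p = 0.0036), was the 1 gene past the threshold in limma, with 961 unadjusted, and did not pass without TgMFT121 tumour 1 (adjusted p = 0.0765). Brca1 was at -0.38, Rb1 at 0.05, Rbl1 at -0.12 and Rbl2 at -0.34. Run, the name at the end of the title and group cannot be told apart here. Median centring gave 0 genes (667 unadjusted), quantile normalization and the authors' values each 1 higher and 1 lower, and leaving out TgMFT121 tumour 2 or p53coco tumour 1, 3 or 4 gave 4, 7, 13 and 2.

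The differences of Brca1coco and TgMFT121 tumours from the same p53coco tumours correlated at 0.562 across genes, which are not independent replicates. Simulated unchanged groups against those controls gave 0.386 (-0.286 to 0.821). The covariance was 0.126 against a simulated 0.0584. With the controls split between the comparisons the correlation was 0.188 (-0.135 to 0.311 over 20 splits) and the covariance 0.0559. The same sign was shared by 66.0% of genes, against 63.2% in simulation.

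**Figure D4:**
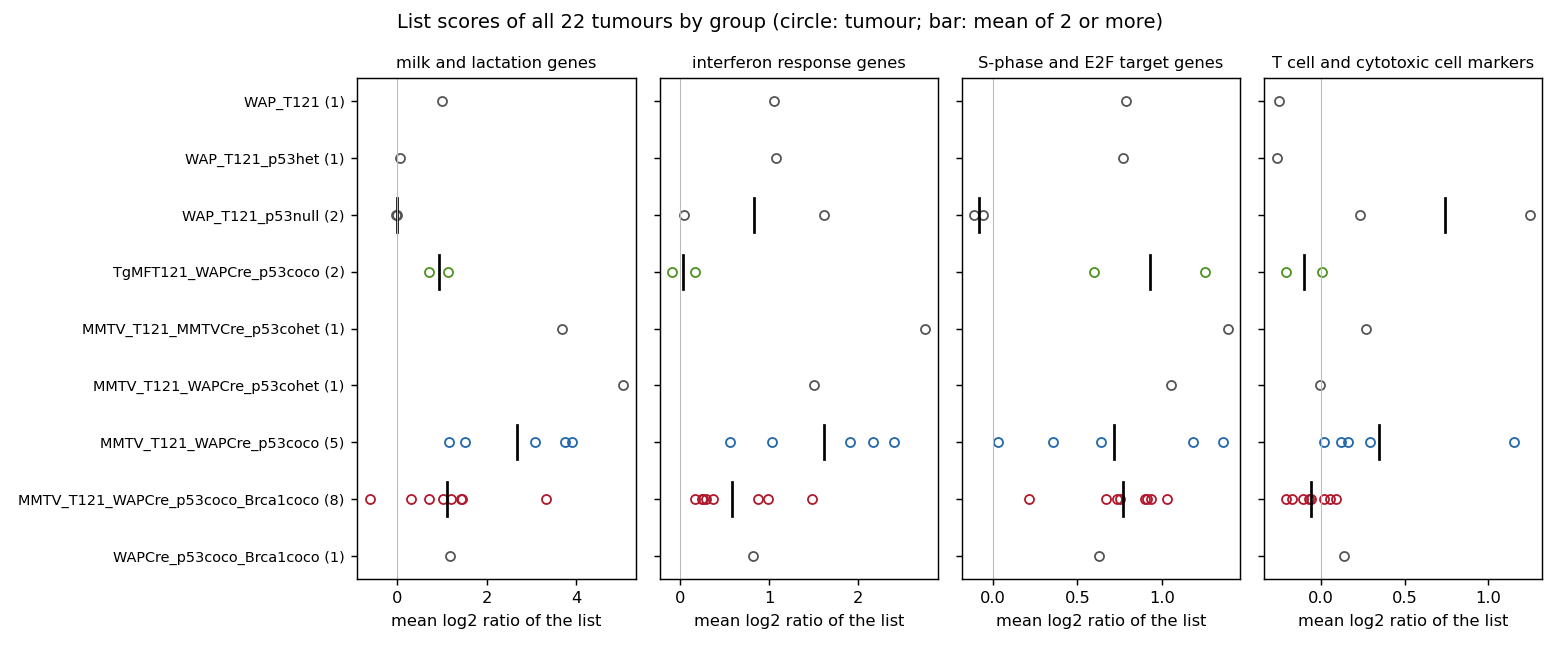
Mean log2 ratio of milk, interferon response, S-phase and T cell lists (x axes) for each of the 22 tumours by group, with the number of tumours in brackets and bars at means of 2 or more. The milk score reached 5.04 in the p53cohet tumour with WAPCre, and the interferon score 2.75 in the p53cohet tumour with MMTVCre.

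p53 dose in WAP_T121 tumours was addressed by 2 p53null tumours against the single p53het tumour. The p53null tumours had lower S-phase and mitotic genes and higher T cell genes. S-phase genes were lower in 25 of 27 members (mean -0.85, camera adjusted p = 0.00169; adjusted p = 0.926 with an estimated correlation), where Pcna fell by 2.79 (SE 0.52, adjusted p = 0.0156) and Tyms by 1.99 (adjusted p = 0.0258), with 4 adjusted over the list alone. Mitotic genes were lower in 25 of 28 (mean -0.88, camera adjusted p = 0.000537; adjusted p = 0.926 with an estimated correlation), where the kinesin gene Kif20a fell by 2.81 (adjusted p = 0.0287), 1 adjusted over the list alone. T cell markers were higher in 9 of 11 (mean 1.01, camera adjusted p = 0.000403; adjusted p = 0.926 with an estimated correlation), where Gzmk, a granzyme, was at least 3.41-fold higher (adjusted p = 0.000494) and Cd3g, of the T cell receptor complex, rose by 1.82 over the list alone, where 2 passed. T cell markers were at 0.50 and did not pass without p53null tumour 2 (adjusted p = 0.0583) or with run as a block, and were at 1.51 without p53null tumour 1. S-phase genes were at -0.55 without background subtraction and -1.39 with median centring, which put mitotic genes at -1.41. Kif20a did not pass without p53null tumour 1, nor Tyms with run as a block. Lists of other cell types did not pass, with luminal markers at -1.28 (11 of 14 lower, camera adjusted p = 0.246), muscle genes at 0.99 (12 of 15 higher, camera adjusted p = 0.0714) and haemoglobins at 1.10 (camera adjusted p = 0.124). Between p53null tumour 1 and the p53het tumour luminal markers differed by -1.07, junction genes by -0.91, basal markers by -0.91, interferon genes by -1.03, adipocyte markers by 1.03, muscle genes by 1.34 and haemoglobins by 1.38.

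Of single genes, Gbp5, an interferon-induced GTPase, rose by 4.66 (SE 1.08, adjusted p = 0.0423) and the urea transporter gene Slc14a2 by 3.95 (adjusted p = 0.0415). Ankzf1 was at least 1.02-fold higher, and Gpnmb passed as higher (adjusted p = 0.000494) although above background in 0 of 2 p53null tumours. Some ratios moved against the tumour channel alone, where the log2 signal of the p53null and p53het tumours was 6.98 and 8.83 for Gpnmb, 13.11 and 13.83 for Slc14a2 and 8.95 and 10.33 for Cd3g. G0s2, an inhibitor of fat breakdown, fell by 4.31 (adjusted p = 0.0109), and the smooth muscle gene Cnn1 (-4.02), Hnrnpf (-3.79) and the histone gene H3f3a (-3.54) fell too. Myo1c, with a value in 1 of 2 p53null tumours and not above background in the p53het tumour, passed as lower, against a tumour channel of 8.54 and 7.51. Rb1, above background in 0 of 2 p53null tumours, was at least 2.47-fold lower in the tumour channel (adjusted p = 0.215), Rbl1 was at -0.60, and Brca1 and Rbl2 were below background in both groups. In limma 164 genes passed, 81 higher and 83 lower (1664 unadjusted). Both p53null tumour 1 and the p53het tumour lay on arrays whose reference channel stood apart, so no fit without those arrays exists. Between these 2 tumours, of run 1, S-phase genes differed by -0.83, mitotic genes by -0.79, T cell markers by 0.50, Pcna by -2.78, G0s2 by -3.64, Slc14a2 by 4.53 and Gbp5 by 2.71. Gbp5 and Cnn1 did not pass without p53null tumour 2, nor Slc14a2 without p53null tumour 1. Median centring gave 21 higher and 549 lower and moved the median of all genes by -0.11, the authors' values gave 18 and 32, and no background subtraction 27 and 14. The count was 626 with run as a block, 330 without the filter, 2624 with quantile normalization, and 474 and 348 without p53null tumour 1 and 2.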

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

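The tests of a lower tumour cell share and of a failed hybridization were chosen only after the result was seen. A tumour's list score is given here where its gap to the nearest tumour of its group, divided by the group's range, exceeded the 95% critical value of Dixon's test. This held in 10 of 46 series of list scores, where about 1 in 20, or 2.3, would be met by chance, and in 0 of 8 series of the genes Brca1, Rb1, Rbl1 and Rbl2.

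p53coco tumour 3 had the lowest luminal score of its group, -0.74 against 1.29 to 1.87 in the other 4 (gap 0.777 of the range), and the lowest junction score, -1.19 against 1.08 to 1.48 (0.848). It also scored 1.46 for muscle (-3.22 ± 0.96, SD, n = 4, in the others), 0.98 for endothelium and 0.64 for fibroblast and matrix genes (-1.07 and -1.72 on average in the others). A lower share of tumour cells in the piece was predicted to raise the markers of every other cell type. Of 8 such lists 6 were highest in this tumour. T cell markers (0.02 against 0.43 ± 0.49, SD, n = 4) and B cell markers (0.10 against 0.81 ± 0.70) lay below the mean of the others, B cell markers by just over 1 SD. That opposes only an even rise of all other cell types, since fewer tumour cells need not mean more lymphocytes. A failed hybridization is opposed by its reference channel, whose rank correlation with the other arrays was 0.984 against 0.946 to 0.979 on the other p53coco arrays. A lower tumour cell share in a piece that took in more muscle and vessels, or a tumour of another histology, stays open. No biological explanation was tested.

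p53coco tumour 2 had the highest T cell score of its group, 1.16 against 0.02 to 0.29 (gap 0.757 of the range). Brca1coco tumour 1 stood apart from the other 7 in 6 lists, lower for S-phase genes (0.21 against 0.67 to 1.03, gap 0.557) and homologous recombination genes (-0.25 against 0.16 to 0.51, gap 0.542). It was higher for basal markers (0.32 against -0.74 to -0.33, gap 0.614), mesenchymal genes (0.32 against -0.75 to -0.43, gap 0.703), endothelial markers (-0.45 against -1.25 to -0.93, gap 0.603) and amplicon oncogenes (0.43 against -0.35 to -0.02, gap 0.569). Brca1coco tumour 3 had the highest adipocyte score, -1.07 against -3.23 to -2.59 (gap 0.704).

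The difference with p53 dose itself differed between WAP_T121 and MMTV_T121 tumours in 86 genes by limma's test of the interaction, 58 higher and 28 lower in WAP_T121 tumours (1561 unadjusted, smallest adjusted p = 0.00358). Milk genes differed by -0.07 with p53 dose in WAP_T121 and by -2.36 in MMTV_T121 tumours, a difference of 2.29 (camera adjusted p = 0.000346; adjusted p = 0.951 with an estimated correlation). The milk score was already low in the WAP_T121 p53het tumour, at 0.06 against -0.005 in p53null, while the MMTV_T121 scores were 5.04 and 2.68. Whether a fall could have shown from that low level was not tested. Adipocyte markers differed by 0.54 and -0.98, a difference of 1.52 (camera adjusted p = 0.0258; adjusted p = 0.951 with an estimated correlation). Each side rests on 1 heterozygous tumour, and 2 of the 3 arrays on the WAP_T121 side had a reference channel that stood apart. The test of the interaction took no account of run. Between tumours of the same run milk genes differed by -0.06 in WAP_T121 and -1.30 in MMTV_T121 tumours, and adipocyte markers by 1.03 and -1.85.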

How the results depend on the processing

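The results with quantile normalization, with the TgMFT121 tumours in place of the p53coco tumours and without the 3 arrays of run 1 were chosen only after the data were seen, as were run as a block together with an estimated correlation and every alternative for the lists outside the Brca1 comparison, and all others were planned. No paired analysis was possible because the labels give no replicate numbers that groups share, and tumours are numbered in the order of their records. Aquantile leaves every log2 ratio as it is (largest change 0), so this planned setting could not move any result and is left out of the counts here. Over all other alternatives, list shifts in the Brca1 comparison kept direction and side of the threshold 466 times, passed newly 39 times, no longer passed 33 times, and turned sign 13 times where a value passed and 70 times where neither did. Lists that passed in the other comparisons kept both 282 times, no longer passed 62 times and turned sign 4 times. Named genes of all comparisons did so 4255, 113, 177, 0 and 113 times. Mgst2 passed in 11 of 26 alternatives (0.21 to 2.51), Xdh in 12 (-2.74 to -0.58) and Glo1 in 10 (-1.48 to -0.20). Signal over background limits calls near the floor, as 15.7% to 83.1% of probes were above it.

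Counts of genes are given as the Brca1, T121, MMTV_T121 p53 dose, WAP_T121 against MMTV_T121, TgMFT121 and WAP_T121 p53 dose comparisons where they moved by over 1.5 times from 3, 2, 55, 139, 1 and 164. The cause was not tested except where fewer or more genes or samples enter by construction. Without background subtraction WAP_T121 against MMTV_T121 gave 90 (42 higher, 48 lower) and WAP_T121 p53 dose 41 (27 higher, 14 lower). Median centring gave 0 for Brca1 (913 unadjusted in limma), 0 for T121 (300), 1 for MMTV_T121 p53 dose, 22 for WAP_T121 against MMTV_T121 (15 higher, 7 lower), 0 for TgMFT121 (667) and 570 for WAP_T121 p53 dose (21 higher, 549 lower). Without the filter, which tests more genes, Brca1 gave 10, T121 28, MMTV_T121 p53 dose 126 and WAP_T121 p53 dose 330. The authors' values gave 0 for T121 (263), 0 for MMTV_T121 p53 dose (780), 214 for WAP_T121 against MMTV_T121, 2 for TgMFT121 and 50 for WAP_T121 p53 dose. Quantile normalization gave 7 for Brca1, 0 for T121 (244), 1277 for WAP_T121 against MMTV_T121, 2 for TgMFT121 and 2624 for WAP_T121 p53 dose. Run as a fixed block gave 0 for Brca1 (923), 1 for T121, 8 for MMTV_T121 p53 dose and 626 for WAP_T121 p53 dose, and as a random block 0 for Brca1 (980, correlation 0.241) and 64 for WAP_T121 against MMTV_T121. Without the 3 arrays of run 1, T121 gave 4, and interferon genes turned to 0.0010 in WAP_T121 against MMTV_T121 tumours.

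For Brca1 the count was 1 with the TgMFT121 tumours added to the controls, 0 with them in place of the controls (1078), 24 within run 9, 7 with all 22 arrays in the fit and 414 with array weights. With an estimated correlation camera called 0 of 23 lists, against 7, and with run as a block too it called 0 (smallest adjusted p = 0.586). With the TgMFT121 tumours in place of the controls the sign turned for mesenchymal genes (-0.14), milk genes (0.17), T cell markers (0.044), interferon genes (0.55), adipocyte markers (0.36), muscle genes (0.82) and hypoxia genes (0.60), of which the last 2 and interferon genes passed, and the cause was not tested. Within run 9 it turned for mesenchymal (-0.017) and squamous genes (-0.36), and with run as a block, under either correlation, for mesenchymal genes (-0.017), where only 5 tumours decide.

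Leaving out 1 tumour at a time gave 0 to 10 genes for Brca1: 0 without Brca1coco 4, 5, 6, 7 or 8 (1001 to 1340 unadjusted), 10 without p53coco 2, 7 without Brca1coco 1, 5 without Brca1coco 2 and 1 without p53coco 4. Lists passing camera ran from 5 (without p53coco 2) to 11 (without p53coco 5), and list scores passing the exact permutation test from 0 to 7 (without p53coco 3; 3 without Brca1coco 3). The fibroblast list ran from -0.55 to 0.23, passing camera at both ends. The endothelial list ran from -0.67 to 0.038. Both were highest without p53coco 3, where muscle genes were at -0.0080. In WAP_T121 against MMTV_T121 tumours interferon genes ran from -1.57 without p53null 2 to 0.0010 without p53null 1, basal markers from -0.038 to 1.92 and T cell markers from -0.11 to 0.90, both lowest without p53null 2 and highest without p53null 1. The T121 count ran from 1, without Brca1coco 2, 3, 4, 6, 7 or 8, to 3. MMTV_T121 p53 dose ran from 35 without p53coco 5 (36 without 3) to 108 without p53coco 1. WAP_T121 against MMTV_T121 ran from 75 without p53coco 4 to 709 without p53null 2, with 81, 317 and 91 without p53coco 2, 3 and 5. TgMFT121 ran from 1 to 13 without p53coco 3, with 4 without TgMFT121 2, 7 without p53coco 1 and 2 without p53coco 4. WAP_T121 p53 dose gave 348 without p53null 2 and 474 without p53null 1, where a lone tumour is assumed to vary like the other groups.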

Other observations

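The tests of array run, of other lines, of Brca1 loss and of another reference RNA were chosen only after the result was seen.

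Of the p53cohet tumours in the MMTV_T121 line, the one with WAPCre had a milk gene score of 5.04. The one with MMTVCre, at 3.69, lay among the p53coco tumours (2.68 ± 1.26, SD, n = 5), of which tumours 1 and 4 scored 3.74 and 3.89, against 1.11 ± 1.12 (SD, n = 8) in Brca1coco tumours. The MMTVCre tumour, which enters no comparison, also had an interferon score of 2.75, an S-phase score of 1.39, a mitotic score of 1.10 and a matrix score of -2.41. The WAP_T121 tumour with no p53 genotype in its label, also in no comparison, scored 1.05 for interferon, 0.79 for S-phase and -0.25 for T cell genes, with Rb1 at 2.32 and Brca1 at 0.57 on an array whose reference channel stood apart. The tumour without T121 scored 0.62 for S-phase genes and 0.33 for mitotic genes, against 0.77 ± 0.25 and 0.58 ± 0.25 (SD, n = 8) in Brca1coco tumours with T121. Apart from the group means, these are values of single tumours. The milk list of the WAPCre tumour and the S-phase and mitotic lists of the tumour without T121 were tested in the comparisons above. Those of the tumour without T121 did not pass. The other values of single tumours were not tested here.

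For the 3 genes that passed in the Brca1 comparison, 4 of 100 splits of the 13 tumours, the real split included, gave as many, while the other 96 gave 0. That is below the bound of 5 set beforehand, but by only 1 split of a random draw. The splits also take no account of array run, so the count does not exclude chance. The highest other split gave 77, several times the real count, which points to a structure of the samples that was not identified. Its group of 8 held all 5 p53coco tumours and all 5 tumours of run 9, but another split of that make-up, which differs in 1 Brca1coco tumour, gave 0 genes and 3 lists. A count past a threshold can change with 1 tumour, so the part of genotype and run in the 77 stays open. The split of the tumours by run 9 against the other runs gave 41 genes and 4 lists. With run as a block limma called 0 genes (923 unadjusted), with Mgst2 at 2.49 (SE 0.57) against 2.30 (SE 0.34), Xdh at -2.31 (SE 0.58) against -2.43 (SE 0.35) and Glo1 at -1.37 (SE 0.34) against -1.38 (SE 0.20). These calls ended because the errors grew where only 5 tumours decide, which is no evidence that run made the differences. For the 7 lists that passed camera, 63 of 100 splits gave as many, with 17 in the highest other split and 8 in the median one, so chance cannot be excluded for the number of lists.

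A first pattern is made of the 20 genes named by the rule in the Brca1 comparison, of which 3 passed, and of its lower interferon, adipocyte and milk lists, which passed camera but not with an estimated correlation (adjusted p = 0.477 for each) or by the exact permutation test of their scores (adjusted p = 0.119, 0.119 and 0.193). Array run as the whole account was tested for interferon genes by the fit with run as a term. The 95% interval of the shift ended at -0.0914, below 0, the result predicted if run were not the cause. The shift rests on the 5 tumours of run 9. There Brca1coco scored 0.28 ± 0.02 (SD, n = 2) and p53coco 1.55 ± 0.86 (SD, n = 3). The interval also takes its spread from the Brca1coco tumours of runs 7 and 8, and ends near 0. The test therefore cannot decide on array run. Strain variants flanking the Brca1 allele are opposed as an account of most of the 20 genes. Only 1 of them was among the 100 tested genes nearest to Brca1 on chromosome 11. Such variants stay open for that 1 gene, and variants elsewhere in the mixed strain were not tested. A difference of the p53coco tumours from other lines, with or without Brca1 loss, and Brca1 loss itself cannot be told apart: TgMFT121 tumours moved the same way in a median of 70% of the 20 genes picked in each split of the controls (35% to 100% over 20 splits). Of the 20 genes, 4 kept the direction and at least 0.5 of the size against TgMFT121 tumours, few enough to exclude Brca1 loss by the bound set, but 5 and 8 did so against each TgMFT121 tumour alone, a spread added after the count was seen that leaves it open.

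Another pattern is that the reference channel of the 3 arrays of run 1 stood apart, although all arrays were labelled as carrying the same RNA. Dim signal was tested on the top quartile of probes by brightness on the 19 other arrays. There the rank correlation reached 0.702, against a lowest value of 0.778 on the 19 others. That opposes dim signal for the WAP_T121 and p53het tumours, with 96.4% and 67.6% of probes above background in the reference channel. It stays open for p53null tumour 1, where those probes may still be dim. Spots read at shifted positions are opposed by a search of up to 500 positions each way, in which 0 of the 3 arrays matched better at an offset. A single other reference RNA on all 3 would make them correlate closely with each other. Their pairs were at 0.648 to 0.691, below the lowest pair of the 19 others, 0.907. Noise could also lower these pairs, as 26.7% of probes were above background in the reference channel of p53null tumour 1. The test therefore cannot decide on another reference RNA. A fault of each hybridization or labelling stays open as well, and no biological explanation was tested because the design gives none.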
